A study of Arabidopsis thaliana with 4 samples.

How the data were processed

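Each of the 4 arrays compared shoot apices of ron3 with those of Ler by direct hybridisation, with 1 array per replicate letter (a to d). Per the labels, RNA was isolated with a plant mini kit, 1 µg was amplified and labelled by in vitro transcription with 10 spike-in transcripts added, and the slide was scanned for Cy3 and Cy5. All 4 arrays lay on the same slide. Per the file headers, spots were quantified with Agilent Feature Extraction 10.1.1.1, and the deposited spot and background signals are median pixel brightness in units of intensity. The deposited processed signals, also an intensity, were background-subtracted, detrended and dye-normalised by that software. Its deposited log ratio is the log10 of processed Cy5 over processed Cy3, and its deposited flags are of another kind (other), 0 or 1 per spot and channel. The value table deposited by the authors holds the log2 ratio of the processed signals for 33441 probes, turned to ron3 over Ler on every array and not centred. Its medians were −0.01, −0.12, 0.01 and −0.17 on arrays a to d, and it matched the processed signals to within 5e-06. The 4037 gene probes that it does not list were well above background on 0 arrays.

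Each array held 39102 spots, of which 1417 were controls, and 37478 different gene probes, 23 of them in 10 spots each. Median Cy3 signals were 135, 146, 164 and 129.5 on arrays a to d, with local backgrounds of 47 to 48, and median Cy5 signals were 198, 194.5, 222 and 148, with backgrounds of 79.5 to 83. Over the 4 arrays 43 gene spots carried an outlier flag and 0 were saturated. The number of arrays limits the precision.

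Signals were corrected with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50), from the median spot signal and the median local background, since the deposited signals are medians while a mean spot signal had been planned. Ratios were normalised by loess within each array with controls at weight 0, with no step between arrays. Repeated spots were averaged, and probes entered when well above background for either genotype on at least 2 of the 4 arrays and unflagged on at least 3. The probe with the highest mean intensity stood for its gene. Of the gene probes, 26236 carried a locus identifier, for 25665 loci, and 19246 genes were tested. Of these, 19135 were found in the reference table of assembly TAIR10.1, which was used only for names and neighbours, and 8662 had a symbol there. The 386 genes with more than 1 probe included 31 whose probes were called in opposite directions, none of them among the genes named by the rule below.

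A linear model with a dye effect for each probe was fitted with limma, leaving 2 residual degrees of freedom, moderated with 2.45 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The dye effect passed the threshold for 0 genes (limma), and 2208 genes had an unadjusted p under 0.05 for it. That is a larger share of the genes tested than the 0.05 expected by chance, so the 0 does not show that dye effects were absent. Spreads given with a ratio are the SD of the 4 arrays. For a gene that was well above background on 0 arrays of one genotype, the lower bound of the fold against that background is given.

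The 27 gene lists were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move one way on balance. Camera called 12 lists, 4 up and 8 down. With an estimated correlation it called 0 lists, with 0 at an unadjusted p under 0.05 and a smallest p of 0.125, and fry called 18. The version with an estimated correlation is judged on the 2 residual degrees of freedom, where a call over 27 lists was hardly possible. Its 0 therefore does not speak against a list. Fry does not set a list against the other genes, and 69.8% of all genes tested changed, so its count does not decide either. The calls at the preset correlation thus stand without a check that allows for correlated members. Of 507 list members written down, 491 matched their locus in the reference and 9 had no symbol there. The other 7 had another spelling there and were left out, 5 phosphatase catalytic subunits and 2 heat shock proteins. The cytosolic ribosomal list holds the 7 genes that the reference describes so. The identity of RON3 as SICKLE was taken from general knowledge.

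The tests, lists and alternatives were chosen before the data were examined, except where said otherwise. So was the rule for named genes: RON3, the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold with the same sign on all 4 arrays, and up to 4 members of each list with the smallest p past the threshold. Alternatives were a fit with no dye effect, no background correction, the log ratio of Feature Extraction, the values of the authors, median centring, loess with Aquantile, no filter or a stricter one, the mean of all probes, another moderation, pairs of arrays averaged, and each array left out. A slide block was not run, since there was 1 slide. The workflow was tested on simulated data with 200 changed genes among 19246: it recovered 59.7% of 67 genes changed by 0.5 on the log2 scale, 77.6% of 67 changed by 1 and 95.5% of 66 changed by 2. It made 4 false calls and 0 calls of the wrong sign, called the shifted list, and called 0 of 20 flat lists. The simulation began from normalised ratios, changed few genes and let genes vary independently. It therefore tested neither the normalisation when most genes change nor the list tests when members are correlated. Probes without a locus identifier were kept out of the gene tests because the files do not pair them with genes.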

Results

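Transcript levels in shoot apices of the Arabidopsis thaliana mutant ron3 were compared with those of its control, the accession Ler, on 4 two-colour Agilent arrays. Plants were grown in vitro to growth stage 1.02, and each array held ron3 RNA in one dye and Ler RNA in the other. On arrays a and c ron3 was labelled with Cy5 and Ler with Cy3, and on arrays b and d the dyes were swapped, so that each orientation was covered by 2 arrays. Between 55.5% and 59.5% of the 37478 gene probes were well above background in the ron3 channel, and between 54.2% and 57.0% in the Ler channel. Array d was the dimmest, with a median Cy5 spot signal of 148 against 194.5 to 222 on the others. Across the 19246 genes tested, the ron3 over Ler ratios of any pair of arrays correlated at r = 0.888 to 0.951, a correlation across genes, which are not independent replicates. The labels describe dye swaps with biological replicates but do not say which arrays share an RNA extract. The p-values measure the spread left between these 4 arrays once the dye effect of each probe is fitted, part of which may be technical. The SDs printed with the ratios still hold that dye effect, so they are not the spread behind the p-values. FER4, for example, stood at −1.92, −2.80, −1.73 and −2.85 on arrays a to d.

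RON3, taken from general knowledge to be SICKLE, which the reference lists as SIC (AT4G24500), was lower in ron3 on every array. Its log2 ratio was −2.30 ± 0.08 (SD, n = 4), a 4.92-fold fall (limma, adjusted p = 0.000148), with −2.31, −2.27, −2.21 and −2.41 on arrays a, b, c and d. Both genotypes gave a signal well above background on all 4 arrays. The 1 probe of the locus was not placed relative to the ron3 lesion here, so its fall shows a lower transcript level at the probe and does not locate the mutation. Among the 8 measured neighbouring loci on each side on chromosome 4, changes ran from −0.53 to 1.04, with 8 rises and 5 falls, where 69.8% of all genes tested changed.

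The comparison asked which transcripts differ between the shoot apices of ron3 and Ler, and most of those tested did. It does not separate the mutation from other differences between the samples, such as growth or harvest hour. Of 19246 genes, 7123 rose and 6311 fell in ron3 (limma, adjusted p below 0.05), which is 69.8% of those tested. Of the changed genes 96.2% had the same sign on all 4 arrays, a share that the call itself favours. Rises outnumbered falls here, but with the log ratio of Feature Extraction, the software that quantified the spots, 5998 genes rose and 7394 fell, and with the authors' values 5995 rose and 7393 fell. Most changes were small, with a median absolute log2 change of 0.41 among changed genes. Larger changes were mostly rises: 1159 genes rose and 393 fell at least 2-fold, 356 rose and 29 fell at least 4-fold, and 119 rose and 1 fell at least 8-fold. The count of genes changed at least 2-fold depends on how the signals were processed: it was 1552 here and 2559 from the log ratio of Feature Extraction.

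Among the 15 largest rises, AT5G39670 rose by 5.36 ± 0.42 (SD, n = 4) on the log2 scale, GRX480, a glutaredoxin of salicylic acid signalling, by 5.30 ± 0.59, and PCR1, a cadmium resistance protein, by 5.26 ± 0.44. SAG13, a senescence-associated gene, rose by 5.14 ± 0.51, AIG1, first known as a gene induced by bacterial avirulence, by 5.06 ± 0.11, and LURP1, a gene of the response to downy mildew, by 4.91 ± 0.29. Both glucanase genes BGL2 (PR2) and BG3 were among them, at 4.60 ± 0.51 and 4.53 ± 0.60, as were TAT3, a tyrosine aminotransferase, at 5.01 ± 0.18, BCS1 at 4.95 ± 0.79 and CML37, a calmodulin-like protein, at 4.58 ± 0.83. AT1G13470, AT1G43910, AT5G10760 and AT5G52760 completed the set, with log2 ratios of 5.16, 4.61, 4.60 and 4.49. In Ler, AT5G39670, TAT3, BCS1, CML37 and BG3 were well above background on 3 of 4 arrays and AT5G52760 on 2. The adjusted p of these 15 genes lay between 4.56e-05 and 0.000464.

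Among the 15 largest falls, AT2G33830 fell most, with a log2 ratio of −3.42 ± 0.45 (SD, n = 4). BXL1, a beta-xylosidase of the cell wall, followed at −2.98 ± 0.29, DIN10, a dark-inducible gene, at −2.74 ± 0.22, and SEN1 (AT4G35770), a gene of dark-induced senescence, at −2.68 ± 0.77. NEET stood at −2.40 ± 0.68 and the ferritin FER4 at −2.32 ± 0.58. AT3G15450 at −2.64 ± 1.01, AT3G62550 at −2.58 ± 0.40, MEE14 at −2.50 ± 0.43 and AT1G22570 at −2.41 ± 0.20 also fell, as did SCPL13, a serine carboxypeptidase-like protein, at −2.21 ± 0.04 and WRI4, a regulator of cuticular wax synthesis, at −2.21 ± 0.23. AT1G56300 and AT5G18600 had log2 ratios of −2.27 and −2.25, and RON3 itself was the remaining member. Their adjusted p lay between 0.000137 and 0.00488, each with the same sign on 4 of 4 arrays.

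**Figure D1:**
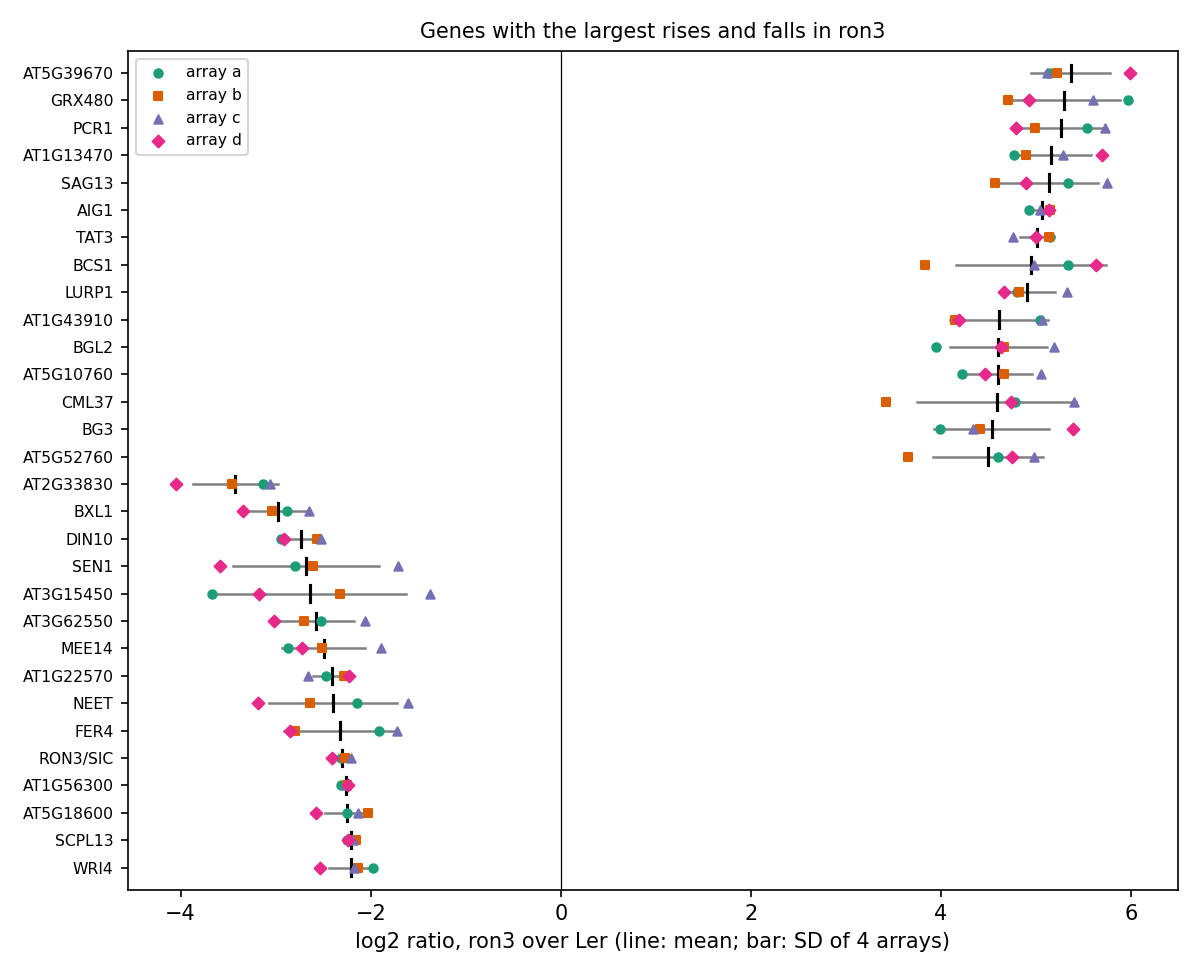
Log2 ratio of ron3 over Ler on each of the 4 arrays for the 15 genes with the largest rises and the 15 with the largest falls. The x axis is the log2 ratio, points are single arrays, the vertical line is their mean and the horizontal bar spans 1 SD either side; RON3/SIC lies near −2.30 on every array, and AT5G39670 has the highest mean, 5.36.

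Salicylic acid and defence genes rose together. All 17 measured members of the list rose, and all 17 did so when adjusted over the list alone. Their median log2 change was 3.52 (camera, adjusted p = 4.43e-07, or 0.658 with an estimated correlation). The estimated correlation leaves the test 2 degrees of freedom, so its adjusted p could hardly pass for any list here. PR1, the classical marker of salicylic acid signalling, rose 17.2-fold and PR5 9.83-fold, with SDs of 0.21 and 0.20 on the log2 scale (n = 4). The transcription factor WRKY38 rose by 2.62 ± 0.22 and SARD1, an activator of salicylic acid synthesis, by 3.85 ± 0.28. Jasmonate response genes rose as well, 13 of 18 measured, with 1 fall and the same counts over the list alone (median 0.84; camera, adjusted p = 0.000797; adjusted p = 0.658 with an estimated correlation). VSP2, a vegetative storage protein, rose by 3.62 ± 0.21, JAZ1, a repressor of jasmonate signalling, by 2.09 ± 0.26, and the jasmonate synthesis enzyme OPR3 by 1.21 ± 0.29. The member that fell was JAZ10, at −0.22 ± 0.14, named after its values were seen.

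Genes of secondary metabolism were higher. The flavonoid and anthocyanin list rose in all 16 measured members, also when adjusted over the list alone (median 1.82; camera, adjusted p = 7.09e-06; adjusted p = 0.658 with an estimated correlation). UF3GT, an anthocyanin glycosyltransferase, rose by 2.96 ± 0.39 (SD, n = 4), the MYB activator PAP1 by 2.67 ± 0.33, chalcone synthase CHS by 2.09 ± 0.16 and F3H by 1.88 ± 0.10. In the glucosinolate list 15 of 20 measured members rose and 2 fell, with the same counts over the list alone (median 0.53; camera, adjusted p = 0.00156; adjusted p = 0.685 with an estimated correlation). The regulator MYB51 rose by 1.37 ± 0.21, and the synthesis enzymes CYP79F1 and CYP83A1 by 1.08 ± 0.17 and 1.02 ± 0.14. The members that fell were the regulators MYB34 at −0.77 ± 0.12 and MYB29 at −0.22 ± 0.17, both named after their values were seen.

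Photosynthesis genes fell almost as a block, while the size of the fall differed between arrays. Of 38 measured members 36 fell and 0 rose, over all genes and over the list alone (median −0.60; camera, adjusted p = 1.70e-08; adjusted p = 0.668 with an estimated correlation). The list mean was −0.45, −0.60, −0.37 and −0.90 on arrays a, b, c and d. DRT112, a plastocyanin, had a log2 ratio of −0.90 ± 0.36 (SD, n = 4), the photosystem II subunit PSBO1 −0.78 ± 0.35, the photosystem I subunit PSAE-1 −0.75 ± 0.13 and the antenna protein LHCA2 −0.69 ± 0.29. The members that did not pass were PRK at −0.04 and PETE1 at −0.04, both named after their values were seen. The falls were larger on arrays b and d, with ron3 in Cy3, than on a and c in the list mean and in DRT112, PSBO1 and LHCA2. For PSAE-1, array b, at −0.69, lay between a and c, at −0.71 and −0.66. Array d, with the lowest mean, was also the array whose root marker mean of −0.07 stood apart from 0.61 to 0.63 on the others.

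Of 27 measured cell cycle genes 23 fell and 0 rose, with the same counts over the list alone (median −0.45; camera, adjusted p = 8.13e-07; adjusted p = 0.658 with an estimated correlation). CDC20.1, an activator of the anaphase-promoting complex, had a log2 ratio of −0.93 ± 0.10 (SD, n = 4), the cytokinesis kinesin HIK −0.85 ± 0.11 and the replication clamp PCNA1 −0.59 ± 0.19. Shoot meristem and leaf patterning genes went both ways: of 27 measured, 9 rose and 11 fell, over all genes and over the list alone (median −0.04; camera, adjusted p = 0.610). The growth regulators ANT and AN3 fell by 0.83 ± 0.12 and 0.73 ± 0.09, the abaxial regulator FIL fell by 0.43 ± 0.11, and KAN3 rose by 0.62 ± 0.09.

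Auxin-responsive genes were mostly lower. In the early response list 17 of 25 measured members fell and 1 rose, with the same counts over the list alone (median −0.74; camera, adjusted p = 7.09e-06; adjusted p = 0.658 with an estimated correlation). The growth-associated genes SAUR22, SAUR19, SAUR23 and SAUR21 had log2 ratios of −1.82 ± 0.18, −1.73 ± 0.11, −1.70 ± 0.13 and −1.63 ± 0.05 (SD, n = 4). These SAUR genes are near-identical neighbours whose transcripts may bind each other's probes, so their separate values are uncertain. The member that rose was IAA17 at 0.26 ± 0.16, named after its values were seen. Of 21 measured auxin transport genes 4 rose and 11 fell, also over the list alone (camera, adjusted p = 0.0983). The influx carrier LAX1 fell by 0.64 ± 0.13, the efflux transporter ABCB19 fell by 0.70 ± 0.18, the kinase WAG1 fell by 0.85 ± 0.17, and PILS3 rose by 0.83 ± 0.17. ABCB4, named after its values were seen, rose 11.3-fold, with an SD of 1.11 on the log2 scale. The mean of that list was 0.00, its median −0.18, and the direction of its test was down. In auxin biosynthesis 6 of 10 measured genes fell and 1 rose, also over the list alone (median −0.25; camera, adjusted p = 0.106): TAR2 and YUC2 fell by 1.31 ± 0.16 and 0.81 ± 0.12, and CYP79B2, which also feeds indole glucosinolates, rose by 1.42 ± 0.27.

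Lists of further growth hormones and of cell wall loosening were tested. Of 15 measured cytokinin genes 11 fell and 2 rose, also over the list alone (median −0.67; camera, adjusted p = 0.00314; adjusted p = 0.658 with an estimated correlation). The response regulators ARR6, ARR7 and ARR15, whose transcripts are induced by cytokinin, had log2 ratios of −1.75 ± 0.13, −1.56 ± 0.07 and −1.55 ± 0.13 (SD, n = 4), and the synthesis gene IPT3 −0.90 ± 0.15. Of 11 measured gibberellin genes 8 fell and 2 rose, also over the list alone (median −0.39; camera, adjusted p = 0.0272; adjusted p = 0.658 with an estimated correlation). GASA6 and GASA4, both gibberellin-regulated, fell by 1.37 ± 0.22 and 1.36 ± 0.09. This list's call ended with the log ratio of Feature Extraction (adjusted p = 0.0504) and with the authors' processed values (0.0506), where its median was lower, at −0.64 in both. It also ended when every probe had to be above background in all channels (median −0.23, adjusted p = 0.150). Of 10 brassinosteroid genes 5 fell and 2 rose, also over the list alone (median −0.27; camera, adjusted p = 0.171), with CPD and BRI1 at −0.63 ± 0.02 and −0.50 ± 0.11. Among 17 expansins and xyloglucan endotransglucosylases 6 rose and 7 fell, also over the list alone (median 0.07, mean 0.01, camera direction down, adjusted p = 0.777), with XTH4 at −1.35 ± 0.12, EXPA8 at −1.32 ± 0.18 and XTH24 at 1.21 ± 0.21.

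Clock genes moved apart. Of 22 measured members 7 rose and 12 fell, also over the list alone, and the list as a whole was not called (median −0.28; camera, adjusted p = 0.171). The morning-expressed MYB factors RVE8, LHY and CCA1 rose by 1.86 ± 0.12, 1.54 ± 0.08 and 1.32 ± 0.04 (SD, n = 4). GRP7, an RNA-binding protein under clock control, fell by 1.58 ± 0.16. Among members named after their values were seen, PRR5, FKF1, PRR7, LUX and PRR9 fell, with log2 ratios of −1.40 ± 0.12, −1.08 ± 0.25, −0.97 ± 0.07, −0.68 ± 0.15 and −0.27 ± 0.14, and the evening gene TOC1, at −0.20 ± 0.18, did not pass (adjusted p = 0.0808). Of 15 measured flowering time genes 5 rose and 4 fell, also over the list alone (median 0.03; camera, adjusted p = 0.777). FT, the mobile flowering signal, rose by 1.17 ± 0.34 and was well above background in Ler on 2 of 4 arrays, FUL rose by 0.68 ± 0.30, and FLM fell by 0.48 ± 0.12. TSF was not well above background on any Ler array and was at least 1.23-fold higher in ron3 (adjusted p = 0.00108).

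**Figure D2:**
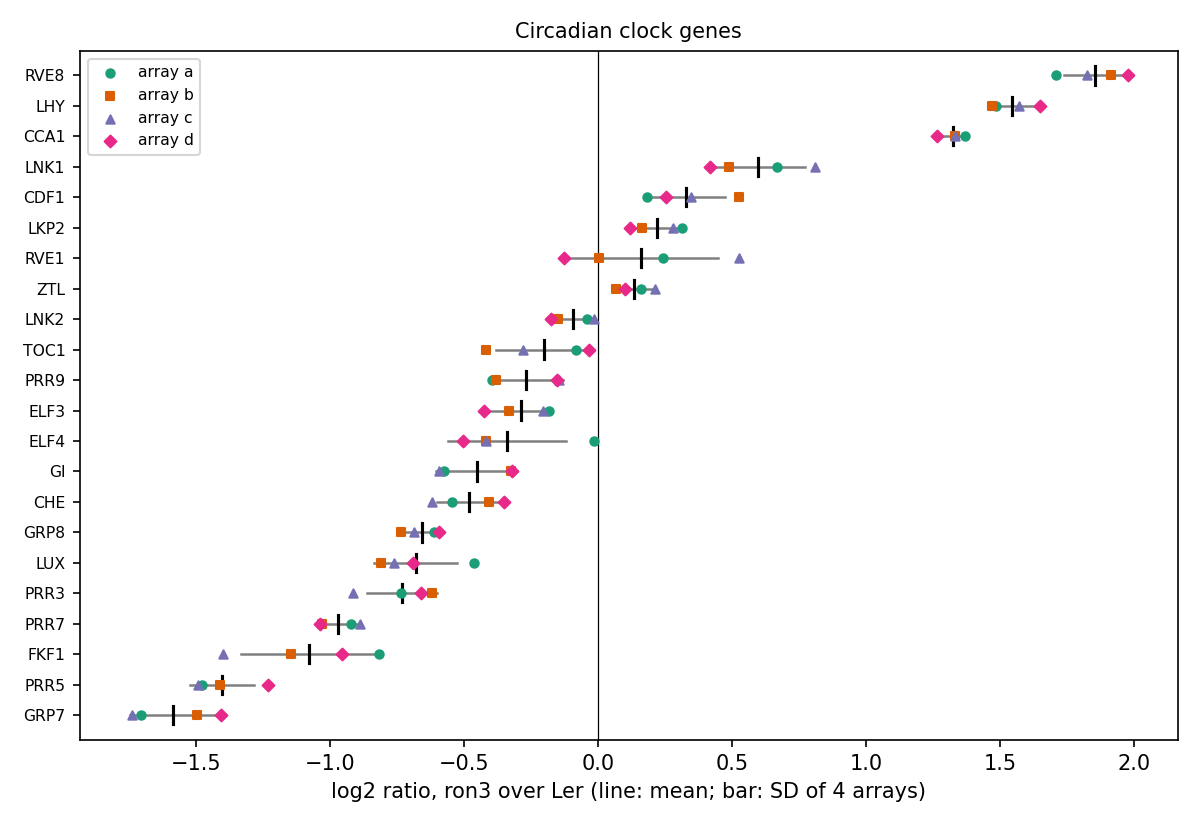
Log2 ratio of ron3 over Ler on each of the 4 arrays for the 22 clock genes, ordered by their mean. The x axis is the log2 ratio, points are single arrays, the vertical line is their mean and the horizontal bar spans 1 SD either side; RVE8, LHY and CCA1 lie at the top with means of 1.86, 1.54 and 1.32, and GRP7 at the bottom with −1.58.

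RON3 has been linked to microRNA maturation, splicing and protein phosphatase 2A, and lists for each were tested. MicroRNA targets were lower on balance, with 33 of 58 measured falling and 10 rising, and 34 and 10 over the list alone (median −0.15; camera, adjusted p = 0.00187; adjusted p = 0.658 with an estimated correlation). SNZ, MYB33, HAM2 and GRF1 had log2 ratios of −0.99 ± 0.13, −0.69 ± 0.06, −0.77 ± 0.07 and −0.68 ± 0.14 (SD, n = 4). CSD1, a copper/zinc superoxide dismutase named after its values were seen, rose by 1.28 ± 0.22. Of 13 microRNA biogenesis genes 2 rose and 4 fell, also over the list alone (median −0.07; camera, adjusted p = 0.505), with HEN1 at −0.38 ± 0.05, AGO1 at −0.33 ± 0.04 and CPL1 at 0.37 ± 0.10. Of 15 phosphatase 2A subunits 3 rose and 4 fell, and 2 and 4 over the list alone (median −0.01; camera, adjusted p = 0.639); the falls were the regulatory subunits B'DELTA at −0.56 ± 0.12, B'ALPHA at −0.55 ± 0.11, B'ZETA at −0.53 ± 0.07 and B'EPSILON at −0.38 ± 0.05. Among 8 splicing factors 2 rose and 2 fell, also over the list alone (median −0.10; camera, adjusted p = 0.610), with PTB1 at −0.70 ± 0.05 and PTB2 at −0.25 ± 0.11.

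Markers of other tissues were examined for differences in what the dissected apices held. Root and root hair markers were higher on arrays a, b and c, with list means of 0.61, 0.63 and 0.62, and stood at −0.07 on array d. Over all arrays 7 of 11 measured rose and 0 fell, also over the list alone (median 0.39; camera, adjusted p = 0.106); without array d the list passed the threshold (median 0.56, adjusted p = 0.00668). The iron transporter IRT1 rose by 1.43 ± 0.51 (SD, n = 4) and CASP1, of the endodermis, by 0.72 ± 0.31. Stomatal lineage and guard cell markers fell in 8 of 9 members, also over the list alone (median −0.33; camera, adjusted p = 0.00223; adjusted p = 0.658 with an estimated correlation), with SDD1 at −0.80 ± 0.10 and MUTE at −0.64 ± 0.10. Vascular markers fell in 9 of 12, also over the list alone (median −0.33; camera, adjusted p = 0.011; adjusted p = 0.658 with an estimated correlation), with XCP1, a xylem protease, at −1.04 ± 0.33 and IRX3 at −0.57 ± 0.19. Of 5 measured trichome markers 2 rose and 2 fell, also over the list alone (median −0.09; camera, adjusted p = 0.682), with GL1 at −0.71 ± 0.04 and TTG1 at 0.47 ± 0.07.

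Stress genes outside the defence lists showed no common direction. Of 20 measured cold, drought and abscisic acid genes 6 rose and 7 fell, also over the list alone (median −0.09, mean 0.27, camera direction down, adjusted p = 0.777). ZAT10, a zinc finger repressor, rose by 3.71 ± 0.47 (SD, n = 4), RD20 by 1.55 ± 0.15 and ADH1 by 0.73 ± 0.07, while the cold regulator CBF3 fell by 1.36 ± 0.20. Of 7 measured heat shock genes 1, HSP18.2, fell by 0.47 ± 0.17 and 0 rose, also over the list alone (median −0.04; camera, adjusted p = 0.610). Of the 7 cytosolic ribosomal protein genes that the reference describes as such, 2 rose and 0 fell, and 1 and 0 over the list alone (median 0.15; camera, adjusted p = 0.288), with RPL18AA at 0.62 ± 0.06.

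**Figure D3:**
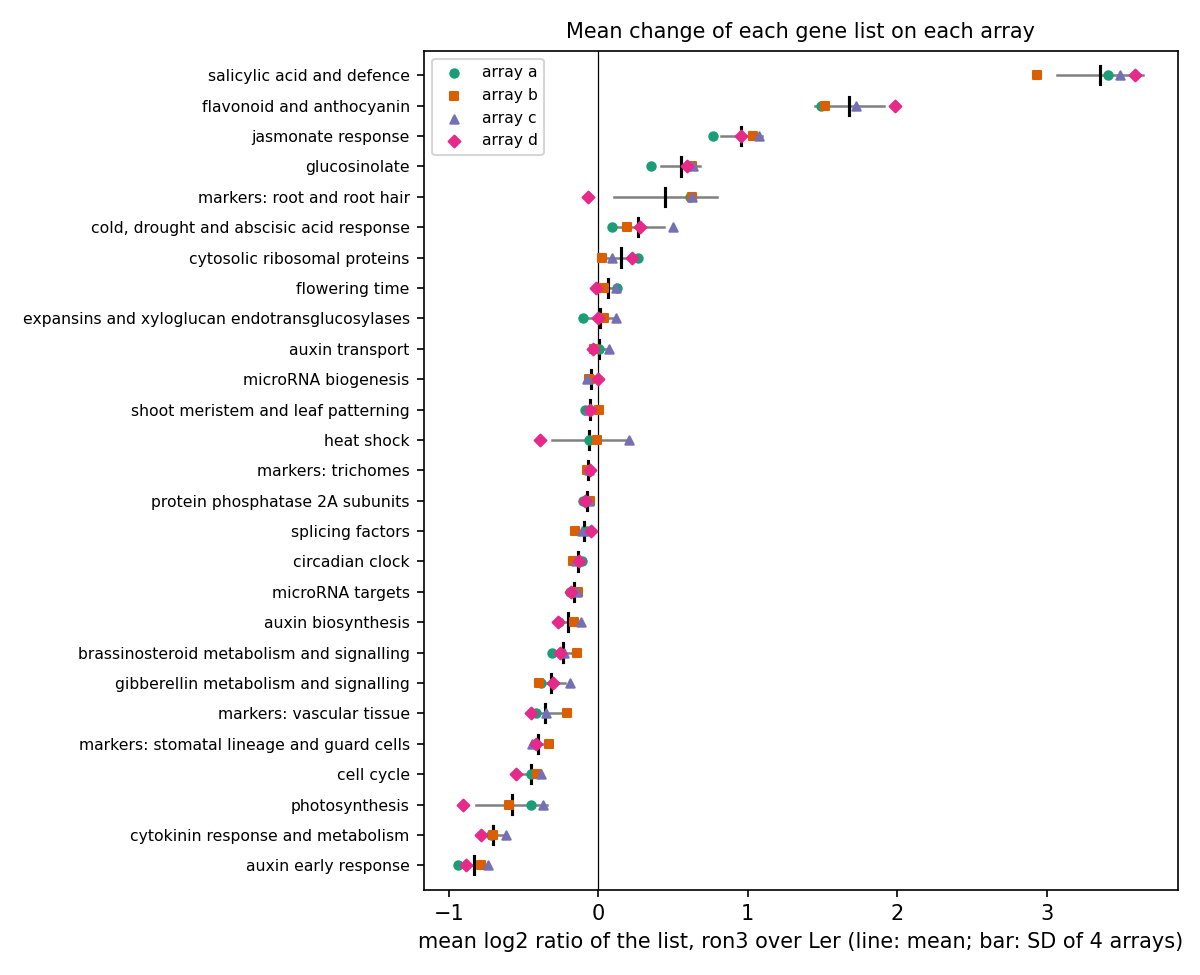
Mean log2 ratio of ron3 over Ler of each of the 27 gene lists on each array. The x axis is the list mean, points are single arrays, the vertical line is the mean of the 4 arrays and the horizontal bar spans 1 SD either side; salicylic acid and defence lies highest, with a mean of 3.36, auxin early response lowest, with −0.83, and the root markers of array d lie at −0.07, apart from 0.61 to 0.63 on the others.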

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

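The tests of other sign patterns, dye orientation, cell cycle, root and vascular markers and harvest hour, and the use of the planned averages of pairs as a test of shared extracts, were chosen only after the results were seen, while those of random lists of equal brightness and of further dawn genes were written down before their results were seen.

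Most tested genes changed, 13434 of 19246. There were 7 sign patterns of the 4 arrays that could be fitted, too few for a share under 0.05. As many genes passed in 1 of them, the real one, and the highest other count was 0 (limma), where 3 to 172 genes had an unadjusted p under 0.05. In the other patterns the difference between genotypes enters the residual spread, so low counts were set in advance and do not speak against chance. Counting arrays that share an extract as separate replicates is argued against as the source of most calls for the pairings tried. There the smaller count with pairs averaged was 12266. Averaging could not show whether all 4 arrays shared an extract of each genotype, and pairing a with c and b with d was not run. The ratios of the dye orientations correlated at 0.954 across genes, which argues against dye bias as the source of most calls. A large genotype effect gives such a correlation even where single genes have dye effects, so it does not exclude those. The dye effect passed the threshold for 0 genes, and 2208 of 19246 had an unadjusted p under 0.05 for it (limma). That is a larger share than the 0.05 expected by chance, so single genes may have dye effects that were not called. The labels speak of biological replicates and do not say which arrays share an extract.

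Photosynthesis genes fell together, with a median of −0.60. More dividing tissue in place of green tissue would raise cell cycle genes, whose median was −0.45, which argues against it; the meristem list, with 9 rises, 11 falls and a median of −0.04, does not decide on a larger share of meristem. Dilution by root tissue also stays open: root markers rose in 7 of 11 members and fell in 0 (median 0.39, and 0.56 without array d, where the list was called), while vascular markers, which roots also hold, had a median of −0.33, and on array d the root markers had a mean of −0.070 where the photosynthesis mean was lowest, at −0.90. A bias of bright probes is argued against by random lists of equal brightness: the list's median lay at percentile 0 of 10000 such lists, whose median was −0.08 and 5th percentile −0.31. Those lists drew genes independently, while the estimated correlation of the photosynthesis members was 0.92. The percentile may therefore overstate how unusual the median is. A difference in growth or leaf age between the genotypes stays open and was not tested.

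Clock genes moved apart, with RVE8, LHY and CCA1 up and PRR5, PRR7 and GRP7 down. The 6 further genes that peak around dawn had a median of 0.40, above the 95th percentile of random lists of equal brightness (0.33). Those lists drew genes independently and ignore that dawn genes can move together, so the percentile may overstate how unusual the median is. RVE2, COL1, COL2 and LNK3 rose by 0.95, 1.13, 0.38 and 0.42, LNK4 stood at 0.11, and EPR1 fell by 1.47. The labels gave a harvest hour for 0 samples, so an earlier clock phase, a later one and a different harvest hour of the genotypes cannot be told apart.

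For 10 of 160 results 1 array lay far from the other 3, or 6.25%, where chance gives about 1 in 20. Array a was the far one in 4, array d in 4, and arrays b and c in 1 each. On array d AT5G39670 was at 5.99 against a mean of 5.16 on the others, IRT1 at 0.67 against 1.69, and PSAE-1 at −0.94 against −0.69. On array a AT1G56300 was at −2.32 against −2.25, SAUR19 at −1.89 against −1.67 and AGO1 at −0.39 against −0.31. SAUR21 on array b was at −1.55 against −1.66, and GL1 on array c at −0.66 against −0.73. The mean of the root and root hair markers was −0.070 on array d against 0.62, and that of the glucosinolate list 0.35 on array a against 0.62.

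Probes without a locus identifier also held a signal. Of 11242 such probes 2050 were tested, and 1100 changed, 551 up and 549 down (limma, adjusted p below 0.05). That is 53.7%, a smaller share than the 69.8% of tested genes that changed. At least 2-fold changes were seen for 61 of them, 46 up and 15 down.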

How the results depend on the processing

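The alternative that kept the 7 list members with another spelling was chosen after seeing the data, and it called 12 lists. RON3 was lower and past the threshold under every alternative run, from −2.76 to −2.23 (adjusted p from 6.04e-06 to 0.00265). No named gene or list called here turned its direction; among all genes called here, 2 were called the other way with the log ratio of Feature Extraction and 7 with the mean of all probes. Genes changed at least 2-fold numbered 2559 with the log ratio of Feature Extraction and 2553 with the authors' values, against 1552. Among genes at least 2-fold apart here, called or not, log2 changes there were 1.22 times as large (slope across those genes), and the cause was not tested. With an estimated correlation camera called 0 lists against 12, with 0 at an unadjusted p under 0.05, and fry called 18. Both the estimate of the correlation and its test rest on 2 residual degrees of freedom. A call over 27 lists was therefore hardly possible, and the 0 decides neither way.

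With 1 array left out, genes changed ranged from 10035 to 13245, rises from 5238 to 7034, falls from 4689 to 6211, changes of at least 2-fold from 1471 to 1667, RON3 from −2.33 to −2.27, named genes past the threshold from 128 to 133 and lists from 12 to 13. Rises outnumbered falls in the main result and with median centring (6882 and 5106) but not with the log ratio of Feature Extraction (5998 and 7394). The median of all genes moved to −0.04 and 0.06 at most, from 0.02. Of 132 named genes besides RON3, 126 kept their direction and call under every alternative that tested them; the others were PRP3, RS2Z33, PFL, DCL1, COBL9 and SR30. Of 27 lists, 8 did so. The 12 called here did not, since each lost its call with the estimated correlation, which could hardly call any list. The gibberellin list lost its call with Feature Extraction's ratio, with the authors' values and with the stricter filter (adjusted p = 0.0504, 0.0506 and 0.150), and the root list gained one without array d (0.00668). Fry, which does not set a list against the other genes, also called 6 lists that camera did not. Aquantile moves no ratio and says nothing about stability, and the slide block was not run. Signal over background limits the genes with a dim genotype, such as TSF and FT.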

Other observations

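The tests of gene families, and the values of the TPS genes, AKINBETA1, ATL8, BZIP1 and ASN1, were chosen only after results were seen, while the test of 12 further starvation genes was written down before its result was seen.

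Gene families that share a symbol stem added further groups. Of 195 families with at least 8 members, camera called 28, 13 up and 15 down, and 0 with an estimated correlation (smallest adjusted p = 0.919). On 2 residual degrees of freedom that version could hardly call any of 195 families, so its 0 speaks neither for nor against them. WRKY transcription factors rose in 36 of 54 members and fell in 5 (median 0.66, adjusted p = 0.000544), led by WRKY51 at 4.26 ± 0.73 (SD, n = 4), WRKY70 at 3.88 ± 0.30 and WRKY46 at 3.73 ± 0.60. Among transporters of the ABCC family 13 of 14 rose (median 0.98, adjusted p = 0.00181), with ABCC3 at 3.65 ± 0.72, and in the RLP family of receptor-like proteins 30 of 39 rose and 5 fell (median 0.58, adjusted p = 0.00221), with RLP38 at 3.28 ± 0.28. Glutathione transferases of the GSTU family rose in 18 of 24 members and fell in 2 (median 0.59, adjusted p = 0.0093), with GSTU24 at 3.47 ± 0.53. NAC and ERF transcription factors rose in 30 of 53 and 16 of 23 members and fell in 11 and 4 (adjusted p = 0.0426 and 0.0397).

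The families called down were likewise not called with an estimated correlation (camera, adjusted p = 0.919), a test that could hardly call any family. Among them all 14 PTAC genes, of the plastid transcription complex, fell (median −0.68, adjusted p = 0.000212), with PTAC16 at −0.98 ± 0.23 (SD, n = 4). So did 10 of 11 CRR genes, required for plastid electron transport (median −0.70, adjusted p = 0.00633), with CRR6 at −1.64 ± 0.17. All 8 MCM genes, of the replicative helicase family, fell (median −0.42, adjusted p = 0.0104), with MCM2 at −0.46 ± 0.13. KCS enzymes of wax and very long chain fatty acid synthesis fell in 13 of 17 members and rose in 2 (median −0.37, adjusted p = 0.0111), with KCS12 at −1.71 ± 0.44.

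Several of the largest falls, DIN10 and SEN1 among them, are genes known to be induced by darkness or sugar starvation. A hypothesis is that this response was lower in the ron3 apices. Of 12 further such genes 9 fell and 1 rose, and their median of −0.28 lay at percentile 2.73 of random lists of equal brightness (5th percentile −0.23). The hypothesis had predicted a median below that 5th percentile, which was met. The random lists drew genes independently and ignore that members of a list can move together, so the percentile may overstate how unusual the median is. BGAL4, DYL1, DIN4, MCCA and ATG8E fell by 1.72, 1.01, 0.83, 0.81 and 0.76, and BCAT2 rose by 1.28. Among genes that had already been seen, TPS8, TPS9, TPS10, TPS11, AKINBETA1, ATL8 and BZIP1 fell by 1.14, 0.71, 0.58, 1.89, 0.94, 0.90 and 1.40, and ASN1 stood at −0.28 without passing. A different harvest hour of the genotypes would also move such genes and stays open.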
